A study of Homo sapiens with 6 samples.

How the data were processed

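RNA sequencing was deposited for 6 libraries of cells labelled NCI-H1703, a human lung squamous cell carcinoma line per the labels. The labels put 3 libraries in the control group and 3 in a group carrying a short hairpin RNA (shRNA) against PPM1G. Total RNA was extracted with a column kit and libraries were made with a SMARTER mRNA kit, per the labels' protocols. The control libraries carry the genotype label Sh-NC, which the labels do not spell out, whereas the series title and design text call the control cells wild-type. They are called control libraries here. The number and sequence of the hairpins, the culture each library came from, the strand setting, the aligner, the counting program and the annotation are not given in the sources used here. The reads were processed against GRCh38, per the submitters' processing notes.

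The deposited count table holds whole-number counts per gene and library, which the authors left without normalization, as judged from the values. The deposited FPKM table holds FPKM values for the same 17534 genes. Each FPKM value was the deposited count divided by 1 length per gene and by the library total, and the factor differed between libraries by a relative spread of at most 5.69e-07. Replicates were not pooled. Genes are identified by symbol and by Entrez gene ID, and the tables also carry KEGG pathway annotation. No gene encoded by the mitochondrial genome was among the genes analysed here. Of the genes in the tables, 446 had 0 counts in all 6 libraries.

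Gene positions, biotypes, lengths and GC content came from reference tables of RefSeq and GENCODE on the same genome build. Entrez IDs matched the RefSeq table for 17483 of the 17534 genes, and 17017 genes had a GC value. Library totals ranged from 31337553 to 35838246 counts. Within a group, the counts of every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 2.69 to 6.44 over genes with at least 20 counts in the pair. Each library was therefore counted as its own replicate. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The replicate numbers in the labels do not state a shared day, batch or culture.

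The comparison of PPM1G shRNA with control libraries used edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes passing edgeR's expression filter at its default minimum of 10 counts were kept, library sizes were scaled by TMM factors, and robust dispersion and quasi-likelihood fits were made with the group as the only term. Adjusted p-values are Benjamini-Hochberg values over all genes tested, from edgeR's quasi-likelihood F-test, with a threshold of 0.05. Standard errors of log2 fold changes were computed as the absolute log2 fold change divided by the square root of F. Positive log2 fold changes mean a higher level in the PPM1G shRNA libraries. CPM values are TMM-scaled values, given as mean ± SD over 3 libraries. No spike-in values were analysed here, so all levels are relative within each library, with CPM scaled by TMM factors and FPKM by the plain total. A change in RNA content per cell would not be seen, and the balance of rises and falls depends on the scaling.

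The genes named in the text were set by a rule. It took PPM1G, then the 12 genes with the largest rise and the 12 with the largest fall among genes with a symbol, an adjusted p under 0.05, a mean log2 CPM of at least 3 and no overlap between the groups' libraries. It then took up to 4 members of each gene list with the largest absolute log2 fold change among those past the threshold. Some genes taken by the rule are not reported here. The rule, 45 gene lists written from textbook knowledge, the tests and most alternatives were fixed before the data were examined. The lists cover phosphatases, the cell cycle, DNA damage, RNA processing, translation, metabolism, stress responses, immune signalling, adhesion and growth factor signalling. Others hold markers of lung cancer subtypes and of cell types other than tumour cells. Lists with at least 5 tested members were tested with limma's camera on voom values at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 43 lists tested. The same lists were run with camera at an estimated correlation and with fry. Camera compares the genes of a list with all other genes. Fry's directional p tests whether the genes of a list move, on balance, one way, and its mixed p tests whether they change in either direction, and neither compares the list with other genes.

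The fit was tested on simulated data for 12798 genes, drawn from the means of the control libraries with known changes added. Dispersions and library sizes were those of this comparison. It recovered 77.6% of 49 genes changed by 1.25-fold, 81.6% of 49 changed by 1.5-fold, 96.0% of 50 changed by 2-fold and 96.0% of 50 changed by 4-fold. False calls made up 6.76% of calls over 5 draws, which is above the rate set by the adjusted p threshold. In the real comparison 82.9% of the genes tested were called, a far larger share than was changed at these folds in the simulation. The rates of recovery and of false calls therefore do not show how the fit performs when most genes change. In the simulated data camera found the shifted list, and the list left alone had an adjusted p of 0.66. The correction for length and GC, run on 12761 genes, returned a median of −0.03 for a list with only a simulated trend and −0.54 for a list with a trend plus a shift of −0.5.

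The alternatives were other scaling factors, DESeq2 1.42.0, other filters on low counts, leaving out each library, the replicate number as a block, and limma on log2(FPKM + 1) or log2(FPKM + 0.1). For lists they were the other set tests named above. A fit limited to protein-coding genes of the RefSeq table was added after the data were seen, since the deposited tables give no biotype. Figures were drawn with matplotlib 3.10.9.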

Results

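RNA sequencing was performed on cells labelled NCI-H1703, which per the labels is a lung squamous cell carcinoma line, to compare cells carrying an shRNA against PPM1G with control cells. PPM1G encodes a metal-dependent serine/threonine phosphatase of the PP2C family that is known to act in the nucleus, among others on splicing and transcription elongation factors. There were 3 control libraries and 3 PPM1G shRNA libraries. Control libraries 1 to 3 held 35532927, 35456562 and 35716901 counts. PPM1G shRNA libraries 1 to 3 held 31337553, 35708945 and 35838246 counts. Between 15117 and 15376 genes had at least 1 count per library, and the 10 most abundant genes took 4.96% to 5.47% of the counts.

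The transcript of the targeted gene was examined first in each library. PPM1G (Entrez 5496; chromosome 2, positions 27381199 to 27409591 on GRCh38) had 11411, 10557 and 11157 counts in control libraries 1 to 3, and 5879, 7182 and 6985 counts in PPM1G shRNA libraries 1 to 3. After TMM scaling, the control libraries stood at 333, 308 and 324 CPM and the PPM1G shRNA libraries at 182, 194 and 188 CPM. The means were 321 ± 13 CPM (SD, n = 3) and 188 ± 6.1 CPM (SD, n = 3). PPM1G fell by 0.77 on the log2 scale (SE 0.03), to 0.585 of its control level, with an adjusted p of 3.3e-20 in edgeR's quasi-likelihood test. The PPM1G locus overlaps FTH1P3, a transcribed pseudogene of the ferritin heavy chain gene, and reads from that pseudogene cannot be separated without knowing the counting rules.

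**Figure D1:**
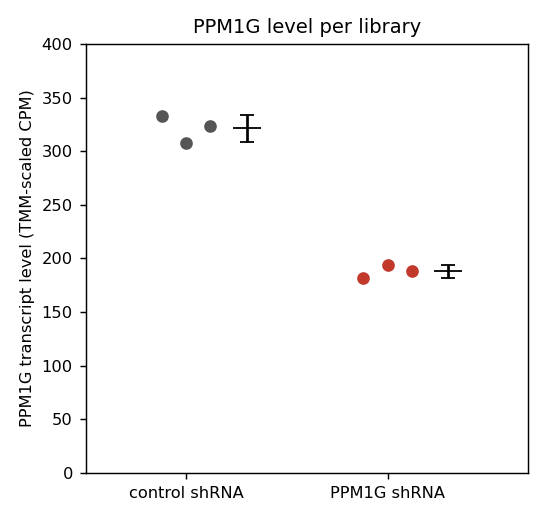
PPM1G transcript level in TMM-scaled CPM (vertical axis) for the 3 control and 3 PPM1G shRNA libraries (points), with the mean (horizontal dash) and SD (bar) of each group beside them. The control libraries lie between 308 and 333 CPM, all above the PPM1G shRNA libraries, which lie between 182 and 194 CPM.

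To determine how the transcriptome differed at this PPM1G level, the groups were compared over 13060 genes. All tested members of the G2/M and mitosis list and of the G1/S and DNA replication list fell, and MAPK feedback, DNA damage and repair, ribosomal protein and oxidative phosphorylation genes mostly fell. Genes of the integrated stress response and interferon-stimulated genes mostly rose. These groups were shifted in camera at a preset correlation, and with an estimated correlation their smallest adjusted p was 0.080. The steepest fall among the genes named by size was that of RRM2, the small subunit of ribonucleotide reductase, from 178 ± 7.3 to 2.13 ± 0.36 CPM. The steepest rise was that of NUPR1, a stress-inducible nuclear protein, from 0.233 ± 0.088 to 15.5 ± 0.66 CPM. With TMM scaling, 10821 genes changed (82.9% of those tested), of which 5422 rose and 5399 fell. Of these, 3158 changed by at least 2-fold, with 1541 rises and 1617 falls, and 4874 (45.0%) changed by less than 1.5-fold. The ranges of the groups did not overlap for 10930 genes (83.7%), where chance gives 10%. The biological coefficient of variation between replicates was 0.0393, so that small differences passed the test. On the log2(FPKM + 1) scale, which understates the change of genes at low levels, limma called 1648 genes at least 2-fold changed.

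Among the 12 named genes with the largest rise, several encode stress-responsive regulators or secreted factors. The transcription factor genes DDIT3 (log2 fold change 3.68 ± 0.08 SE, from 17.7 ± 2.9 to 226 ± 2.5 CPM) and ATF3 (3.34 ± 0.05, from 15.0 ± 0.75 to 152 ± 2.8 CPM) rose with NUPR1 (6.04 ± 0.18). The secreted TGF-beta family members GDF15 (3.85 ± 0.14) and INHBE (3.89 ± 0.09) rose as well. TXNIP, an inhibitor of thioredoxin, rose by 3.69 ± 0.10, from 129.9 ± 16 to 1676 ± 6.7 CPM. CYP1A1, a cytochrome P450 under the aryl hydrocarbon receptor, rose by 4.42 ± 0.06. The others were the neurotrophin receptor gene NGFR (4.37 ± 0.12), the transporter genes SLC16A9 (4.05 ± 0.14) and SLC43A2 (3.88 ± 0.08), PIK3IP1 (3.59 ± 0.12), which encodes a phosphoinositide 3-kinase inhibitor, and PSG7 (4.16 ± 0.11). PSG7 belongs to a family of near-identical genes, so its count is uncertain.

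Among the 12 named genes with the largest fall, RRM2 fell by 6.39 on the log2 scale (SE 0.07). The replication initiation factor gene MCM10 (−5.28 ± 0.14), the cohesion factor gene DSCC1 (−5.15 ± 0.13), the chromatin regulator gene UHRF1 (−4.87 ± 0.09), the exonuclease gene EXO1 (−4.65 ± 0.11) and the mitotic kinesin gene KIF18B (−4.82 ± 0.07) fell with it. FAM111B (−5.72 ± 0.12), TCF19 (−4.65 ± 0.07), MYEOV (−4.73 ± 0.09), the peroxisomal oxidase gene ACOX2 (−5.89 ± 0.14) and the ETS factor gene ETV4 (−4.85 ± 0.12) were also in this group. KRTAP2-3 (−4.57 ± 0.10) has close paralogs that may share its reads. Of PPM1G and these 24 genes, 12 overlap another gene in the RefSeq annotation. For DDIT3, UHRF1 and ETV4 the overlapping gene is protein-coding (MARS1, ARRDC5 and DHX8), and for NGFR, INHBE, SLC43A2, GDF15, RRM2, ACOX2, DSCC1 and KIF18B it is a non-coding RNA gene or a pseudogene. Their levels are uncertain to that extent, since no strand setting is stated. All 24 passed edgeR's test, with adjusted p from 1.8e-35 for RRM2 to 2.1e-06 for TXNIP.

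**Figure D2:**
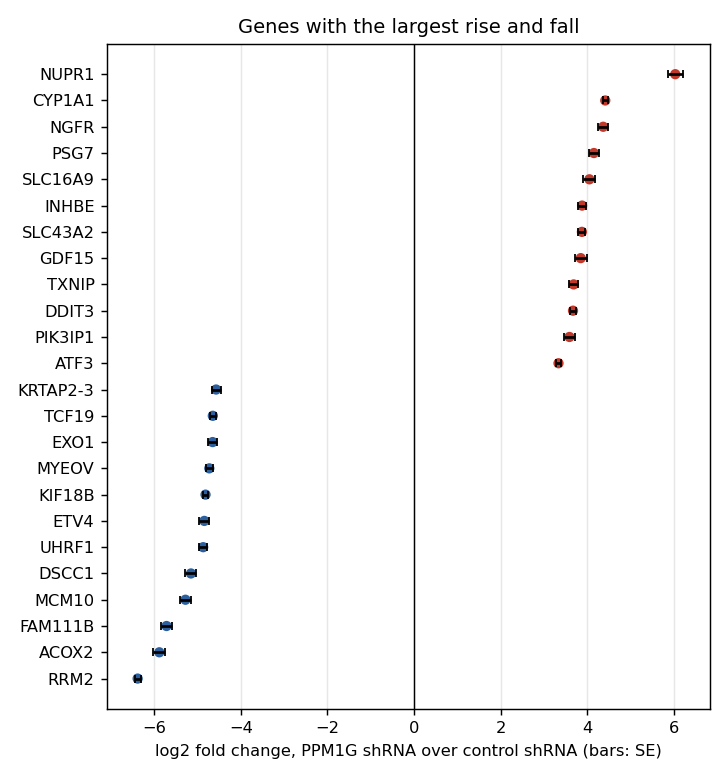
Log2 fold change of PPM1G shRNA over control libraries (horizontal axis) for the 12 named genes with the largest rise and the 12 with the largest fall (points; bars are SE, 3 libraries per group). Values run from −6.39 for RRM2 to 6.04 for NUPR1.

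Gene lists were then compared with all other genes by camera. At a preset correlation 19 of 43 tested lists were shifted, 7 up and 12 down. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.080, while 7 had an unadjusted p under 0.05. Fry found a movement on balance one way in 42 lists and change in either direction in 43, the exception to the former being translation initiation and mTOR (fry adjusted p = 0.92). Counts of members below are over all genes tested, and adjusted over the list alone they were the same except for 1 more rise in each of the TGF-beta and antigen presentation lists. Values after ± are SE of log2 fold changes.

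In the list of G2/M and mitosis genes, 40 of 40 fell, each by at least 2-fold, with a median log2 fold change of −2.79 (camera adjusted p = 3.6e-18; adjusted p = 0.12 with an estimated correlation). AURKB, a kinase of the chromosomal passenger complex, fell by 4.25 ± 0.06, and the proliferation marker gene MKI67 fell by 3.86 ± 0.05, from 509 ± 38 to 35.1 ± 1.5 CPM. CDK1, the mitotic cyclin-dependent kinase, fell by 3.44 ± 0.05, and the separase gene ESPL1 fell by 3.66 ± 0.09. In the list of G1/S and DNA replication genes, 40 of 40 fell, 37 of them by at least 2-fold, with a median of −2.79 (camera adjusted p = 9.6e-16; adjusted p = 0.080 with an estimated correlation). Its largest changes included RRM2, MCM10 and UHRF1. E2F2 had 146 counts over the control libraries and 1 count over the PPM1G shRNA libraries, a ratio of 0.00663 after TMM scaling, with a 95% exact interval of 0.000167 to 0.0375 that covers counting error only.

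DNA damage signalling and repair genes fell in 31 of 40 cases and rose in 4, with a median of −1.23 (camera adjusted p = 5.4e-07; adjusted p = 0.12 with an estimated correlation). EXO1, the recombination genes XRCC2 (−4.24 ± 0.11) and RAD54L (−4.10 ± 0.07) and the helicase gene BLM (−3.97 ± 0.12) had the largest falls. MAPK feedback genes, which are transcribed on ERK activity, fell in 18 of 20 cases and rose in 1, with a median of −1.40 (camera adjusted p = 1.7e-06; adjusted p = 0.097 with an estimated correlation). The ERK phosphatase gene DUSP6 (−3.82 ± 0.09), ETV5 (−3.08 ± 0.06) and SPRY4 (−2.82 ± 0.08) fell. MYC target genes fell in 28 of 38 cases and rose in 7 (median −0.39, camera adjusted p = 0.0016; adjusted p = 0.29 with an estimated correlation), led by the ribosome biogenesis genes BOP1 (−1.51 ± 0.05) and FBL (−1.48 ± 0.04).

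Cytosolic ribosomal protein genes showed a small fall shared by nearly all members. Of 67 tested, 65 fell and 0 rose, with a median of −0.52 (camera adjusted p = 6.9e-14; adjusted p = 0.30 with an estimated correlation). The largest falls were those of RPL6 (−1.06 ± 0.03) and RPS16 (−1.04 ± 0.04). These genes have many processed pseudogenes that may share their reads. Of 47 nuclear-encoded oxidative phosphorylation genes, 41 fell and 0 rose (median −0.50, camera adjusted p = 1.4e-07; adjusted p = 0.34 with an estimated correlation). ATP5MC1, a subunit of the ATP synthase ring, fell by 1.92 ± 0.06, and the complex I gene NDUFS8 fell by 1.73 ± 0.05. Both groups hold short genes, and short genes fell slightly across the whole set, with a median log2 fold change of −0.17 in genes of up to 2225 bp and 0.07 in genes of at least 7233 bp. Hypoxia and glycolysis genes fell in 22 of 36 cases and rose in 10 (median −0.31, camera adjusted p = 0.037; adjusted p = 0.39 with an estimated correlation). The glycolytic genes PGK1 (−2.04 ± 0.03) and PGAM1 (−1.97 ± 0.04) fell, whereas the peptide hormone gene ADM rose by 2.43 ± 0.05. Cholesterol biosynthesis genes fell in 13 of 24 cases and rose in 5 (median −0.34, camera adjusted p = 0.049; adjusted p = 0.43 with an estimated correlation), including ACAT2 (−1.39 ± 0.05) and the farnesyl diphosphate synthase gene FDPS (−1.33 ± 0.05).

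Genes of the integrated stress response, which are activated by the transcription factor ATF4, mostly rose. Of 26 tested, 22 rose, 17 of them by at least 2-fold, and 2 fell (median 1.83, camera adjusted p = 1.4e-07; adjusted p = 0.080 with an estimated correlation). Beside NUPR1 and DDIT3, the asparagine synthetase gene ASNS rose by 2.75 ± 0.03, from 59.0 ± 1.2 to 397 ± 6.5 CPM, and the amino acid transporter gene SLC7A5 by 2.63 ± 0.05. Heat shock protein genes fell in 16 of 22 cases and rose in 4 (median −0.60, camera adjusted p = 0.0030; adjusted p = 0.27 with an estimated correlation). The chaperone genes HSPA8 (−1.89 ± 0.03, from 2851 ± 121 to 767 ± 3.7 CPM) and HSP90AA1 (−1.74 ± 0.03) and the co-chaperone gene STIP1 (−1.67 ± 0.03) had the largest falls, and HSPA8 has pseudogenes that may share its reads. NRF2 and antioxidant genes rose in 20 of 32 cases and fell in 11 (median 0.44, camera adjusted p = 0.037; adjusted p = 0.29 with an estimated correlation). The heme oxygenase gene HMOX1 rose by 2.76 ± 0.03, NFE2L2, which encodes NRF2 itself, by 1.97 ± 0.03, and the cystine transporter gene SLC7A11 by 1.81 ± 0.06, whereas the carbonyl reductase gene CBR1 fell by 2.04 ± 0.05. Target genes of p53 rose in 18 of 29 cases and fell in 8 (median 0.40, camera adjusted p = 0.037; adjusted p = 0.27 with an estimated correlation). GDF15, the pro-apoptotic gene BBC3 (2.17 ± 0.14) and SESN2 (2.15 ± 0.05) led this list, and 8 of its 30 genes also belong to other lists.

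Interferon-stimulated genes rose in 30 of 38 cases and fell in 5 (median 0.85, camera adjusted p = 2.1e-06; adjusted p = 0.13 with an estimated correlation). The antiviral gene MX2 rose by 2.88 ± 0.13, and the interferon regulatory factor genes IRF7 and IRF1 by 2.86 ± 0.09 and 2.64 ± 0.05. NF-kB and inflammatory cytokine genes rose in 21 of 32 cases and fell in 8 (median 0.75, camera adjusted p = 0.027; adjusted p = 0.27 with an estimated correlation). IL6 rose from 0.466 ± 0.19 to 10.8 ± 0.19 CPM (4.53 ± 0.19), whereas the growth factor gene CSF2 fell by 2.85 ± 0.14. YAP/TAZ target genes rose in 14 of 23 cases and fell in 7 (median 0.55, camera adjusted p = 0.049; adjusted p = 0.34 with an estimated correlation), with GADD45B (3.15 ± 0.04) and AJUBA (1.92 ± 0.04) rising and NT5E (−1.58 ± 0.03) falling. Matrix metalloproteinase and protease genes fell in 15 of 23 cases and rose in 5 (median −0.39, camera adjusted p = 0.049; adjusted p = 0.27 with an estimated correlation). The collagenase gene MMP1 fell by 3.22 ± 0.03. Without PPM1G shRNA replicate 1 the adjusted p of the YAP/TAZ, metalloproteinase and cholesterol lists was 0.057, and with CPM of at least 1 required in 3 libraries it was 0.052, 0.068 and 0.063. Without PPM1G shRNA replicate 3 that of the metalloproteinase list was 0.057.

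Regulators of 7SK and P-TEFb, the elongation kinase complex on which PPM1G is known to act, rose in 16 of 23 cases and fell in 3 (median 0.24, camera adjusted p = 0.010; adjusted p = 0.27 with an estimated correlation). The elongation factor gene ELL rose by 1.32 ± 0.05, the 7SK capping enzyme gene MEPCE by 0.91 ± 0.03 and the P-TEFb inhibitor gene HEXIM1 by 0.71 ± 0.05. Spliceosome and SR protein genes fell in 27 of 44 cases and rose in 11 (median −0.27, camera adjusted p = 0.027; adjusted p = 0.34 with an estimated correlation). The Sm core protein genes SNRPD1 (−2.69 ± 0.11) and SNRPB (−1.92 ± 0.05) fell, whereas the splicing kinase genes CLK1 (2.45 ± 0.04) and CLK4 (1.55 ± 0.07) rose. The PP2C phosphatase family, to which PPM1G belongs, had 10 rises and 6 falls among 19 genes and was not shifted as a list (camera adjusted p = 0.20). PDP1, a phosphatase of pyruvate dehydrogenase, rose by 1.38 ± 0.03, and PPM1D by 0.85 ± 0.06. Protein phosphatase 2A subunits and regulators had 8 rises and 14 falls among 24 genes (camera adjusted p = 0.20), including the inhibitor gene CIP2A (−2.49 ± 0.07).

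**Figure D3:**
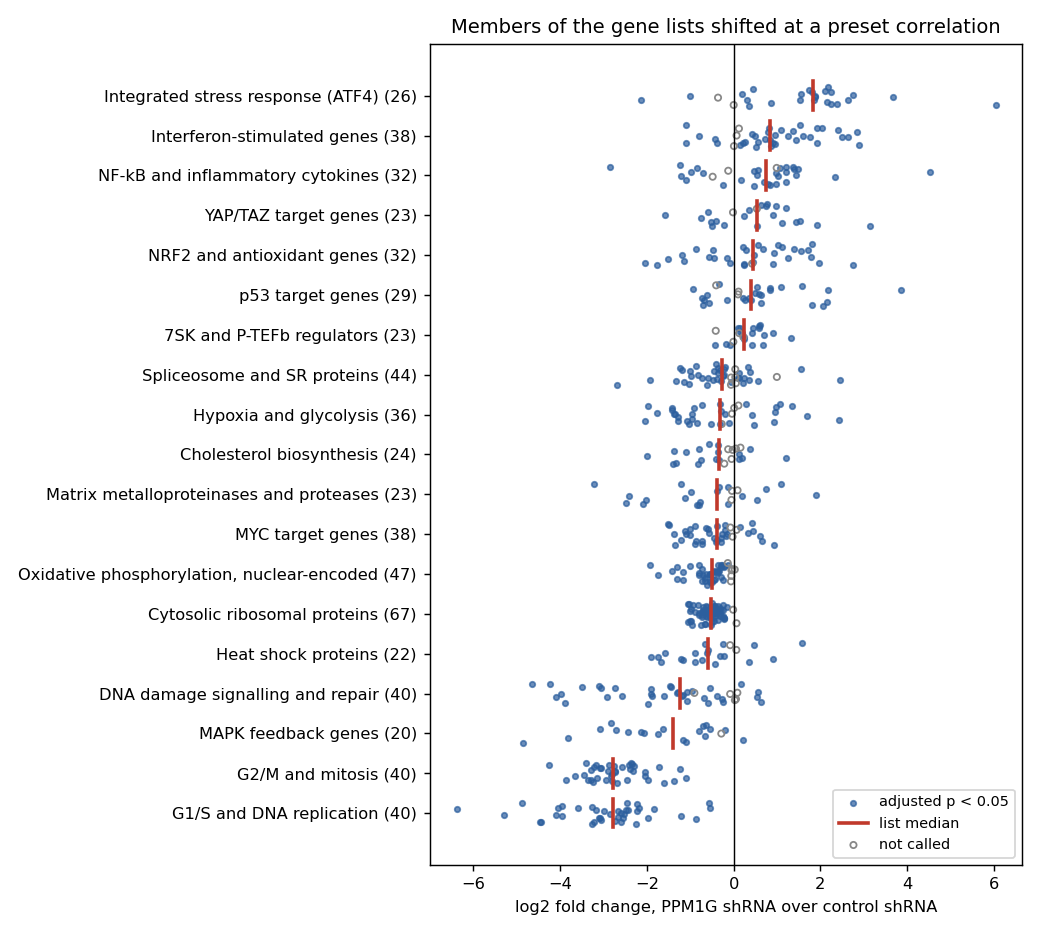
Log2 fold change of PPM1G shRNA over control libraries (horizontal axis) for the tested members of the 19 lists shifted at a preset correlation (1 line per list, the number tested in parentheses). Filled points passed edgeR's test, open points did not, red lines are list medians, and E2F2 is left out because of its single count in the PPM1G shRNA libraries. List medians run from −2.79 for G1/S and DNA replication to 1.83 for the integrated stress response.

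The other tested lists did not pass camera, and their members moved both ways. Immediate early genes had 17 rises and 10 falls among 29 (adjusted p = 0.073), with BTG1 rising by 2.29 ± 0.03 and EGR1 falling (−2.13 ± 0.10). Apoptosis regulators had 17 rises and 11 falls among 32 (adjusted p = 0.36), with the pro-apoptotic gene BMF rising by 2.32 ± 0.07 and the anti-apoptotic gene BCL2 falling (−3.44 ± 0.21). Autophagy and lysosome genes had 20 rises and 10 falls among 33 (adjusted p = 0.073), including the receptor gene SQSTM1 (1.61 ± 0.03). Ferroptosis regulators had 12 rises and 7 falls among 22 (adjusted p = 0.061), including SLC3A2 (2.11 ± 0.03). The unfolded protein response list had 9 rises and 16 falls among 27 (adjusted p = 0.21), including SDF2L1 (−2.70 ± 0.13) and PDIA4 (−1.67 ± 0.04). Fatty acid synthesis genes had 5 rises and 13 falls among 21 (adjusted p = 0.061), including the elongase gene ELOVL6 (−1.47 ± 0.05). Translation initiation and mTOR genes had 13 rises and 16 falls among 32 (adjusted p = 0.69), with EIF5 rising by 1.63 ± 0.03. Replication-dependent histone genes had 5 rises and 5 falls among 13 (adjusted p = 0.76), and these near-identical genes may share reads. Senescence-associated genes had 8 rises and 11 falls among 21 (adjusted p = 0.55), with IL6 rising and the hormone gene STC1 falling (−4.51 ± 0.04).

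Signalling and adhesion lists were likewise divided. Receptor tyrosine kinase and ligand genes had 12 rises and 13 falls among 32 (adjusted p = 0.72), including the ligand gene TGFA (−2.74 ± 0.17). TGF-beta pathway genes had 17 rises and 9 falls among 29, or 18 and 9 adjusted over the list alone (adjusted p = 0.19), with the inhibitory SMAD7 rising by 2.17 ± 0.08 and the activin antagonist FST falling (−2.18 ± 0.10). Wnt pathway genes had 8 rises and 11 falls among 22 (adjusted p = 0.95), including the cyclin gene CCND1, which fell by 2.71 ± 0.03, from 616 ± 19 to 93.9 ± 4.2 CPM. Notch pathway genes had 8 rises and 3 falls among 12 (adjusted p = 0.12), including HEY1 (1.93 ± 0.05). Antigen presentation genes had 15 rises and 7 falls among 24, or 16 and 7 adjusted over the list alone (adjusted p = 0.24), with HLA-E rising by 0.94 ± 0.03 and TAP2 falling (−1.18 ± 0.04). Genes of the epithelial-mesenchymal transition had 8 rises and 7 falls among 21 (adjusted p = 0.69), with SNAI2 (1.12 ± 0.03) and FN1 (1.11 ± 0.02) rising and VIM (−0.88 ± 0.02) falling. Collagen and extracellular matrix genes had 13 rises and 22 falls among 37 (adjusted p = 0.19), with THBS1 rising by 2.58 ± 0.06 and COL17A1 falling (−3.26 ± 0.08). Integrin and focal adhesion genes had 10 rises and 16 falls among 27 (adjusted p = 0.084), including ITGA2 (−2.23 ± 0.03) and ITGA6 (−1.45 ± 0.03). List median and camera direction had opposite signs for the histone, fibroblast and receptor tyrosine kinase lists, as had median and mean for the apoptosis, translation, fibroblast and receptor tyrosine kinase lists.

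Lineage markers were mostly too low to test. Of 30 squamous lineage markers 8 were tested, with 1 rise and 5 falls (adjusted p = 0.20). SOX2, a squamous lineage transcription factor, fell from 22.7 ± 1.5 to 10.6 ± 0.62 CPM, TP63 stood at 1.54 ± 0.35 and 0.836 ± 0.25 CPM, and the keratin gene KRT15 fell by 2.45 ± 0.08. Of 20 lung adenocarcinoma and alveolar markers 9 were tested, with 6 rises and 1 fall (adjusted p = 0.12). The aspartic protease gene NAPSA (3.33 ± 0.11) and KRT7 (2.80 ± 0.14) rose from low control levels. NAPSA went from 2.16 ± 0.23 to 21.8 ± 0.40 CPM and KRT7 from 1.53 ± 0.21 to 10.7 ± 0.68 CPM. Of 22 neuroendocrine markers only 4 were tested, too few for a list test, with SCG2 rising by 2.64 ± 0.15 and ENO2 falling (−0.29 ± 0.05). Of 23 leukocyte markers 7 were tested, with 1 rise and 4 falls (adjusted p = 0.50). Among them CD68, a lysosomal protein gene also transcribed outside leukocytes, fell from 1266 ± 31 to 566 ± 16 CPM. Fibroblast markers had 3 rises and 3 falls among 9 tested of 20 (adjusted p = 0.71), and 11 of the 20 also belong to other lists. COL1A1 rose from 154 ± 9.0 to 344 ± 5.1 CPM. PDGFRA, a member of this list named after its values were seen, had 18 counts over the control and 16 over the PPM1G shRNA libraries and was not tested. Endothelial markers had 2 rises and 5 falls among 8 tested of 14 (adjusted p = 0.50), including PECAM1, which fell from 5.31 ± 0.91 to 1.08 ± 0.22 CPM. The list of 13 mitochondrially encoded transcripts had 0 members in the test.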

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

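The fit limited to protein-coding genes was chosen after the data were seen, and the others were planned. The number of changed genes ranged from 9513 to 11183 over the alternatives, and from 10531 to 10836 with 1 library left out. The number changed at least 2-fold was 1648 on log2(FPKM + 1) and 1624 with a mean FPKM of at least 1 required. By construction that pseudocount shrinks folds of low genes. Over the other alternatives it ranged from 2752 to 3547. On log2(FPKM + 0.1) the median of all genes lay at 0.11, with 6023 rises and 4762 falls, or 1563 and 1197 at 2-fold. On log2(FPKM + 1) there were 6010 rises and 4753 falls, or 847 and 801 at 2-fold. PPM1G ranged from −0.81 to −0.67 on the log2 scale and passed each test. Of 2886 values for the 183 genes taken by the rule, 2882 kept their direction and call, and 4 kept their direction but lost the call: CRYAB without PPM1G shRNA replicate 3, and CSF1R under DESeq2, without control replicate 3 and without PPM1G shRNA replicate 2. Shifted lists numbered 0 with an estimated correlation (7 at an unadjusted p under 0.05) and 42 with fry. Otherwise they numbered 16 to 22. All 19 called lists were lost with an estimated correlation. For some of them the estimate was not above the preset 0.01. It was −0.022 for the integrated stress response, −0.026 for p53 targets and −0.025 for metalloproteinases. For MAPK feedback genes it was 0.010, almost the same as the preset value. A higher correlation between genes therefore does not account for the loss of these lists. In 7 other cases the cholesterol, metalloproteinase or YAP/TAZ list lost its call: with CPM of at least 1 required (adjusted p 0.063, 0.068 and 0.052), without PPM1G shRNA replicate 1 (0.057 for each), and without replicate 3 (metalloproteinases, 0.057). The cause was not tested. With the replicate number as a block, 10805 genes were called, 3159 of them at least 2-fold changed, and 20 lists. Deviations of same-numbered libraries correlated at 0.037, 0.012 and 0.0079. Controls 1 and 2 correlated best with the PPM1G shRNA library of their own number, and control 3 with PPM1G shRNA 2 (0.024). Values this small do not settle whether the libraries were paired. The labels state no pairing, so the numbers were not treated as pairs in the main fit.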

Other observations

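The gene families and pathways in this part, and the tests of reads shared with pseudogenes, of another cell line and of PDGFRA, were chosen only after the results were seen. Other tests had been set before. Genes named ZNF, which mostly encode zinc finger transcription factors, more often rose than fell. Of 446 tested, 318 rose and 70 fell, with a median log2 fold change of 0.61. This group was picked by its values, so no p is given for it. None is given either for the zinc finger families zf-C2H2 (123 tested, 85 rises and 23 falls) and ZBTB (13 tested, 11 rises and 1 fall) of the deposited annotation, which hold genes of the same kind. Among all 8 of its transcription factor families with at least 10 tested genes, the bZIP family (28 tested, 24 rises and 4 falls) had a camera adjusted p of 3.8e-05 at a preset correlation and adjusted p = 0.030 with an estimated correlation, and the 5 families not named here did not pass. For the genes named ZNF the median was 0.59 after a correction for length and GC. ZNF844 rose from 27.3 ± 1.0 to 228 ± 3.9 CPM, ZNF442 rose by 2.97 ± 0.09 (SE) on the log2 scale and ZNF433 by 2.58 ± 0.06, whereas ZNF367 fell by 2.65 ± 0.08. Many of these genes are close paralogs, so single members are uncertain. The aminoacyl-tRNA synthetase genes, also picked after the values were seen, had 11 rises and 9 falls among 20.

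Among 310 KEGG pathways of 10 to 300 tested genes in the deposited annotation, 33 were shifted at a preset correlation. With an estimated correlation 0 passed in camera, the adjusted p being 0.47 to 0.50 for the shifted pathways named here, and 28 had an unadjusted p under 0.05. Proteasome genes fell in 38 of 43 cases and rose in 1 (median −0.53, adjusted p = 3.5e-07), including the catalytic subunit gene PSMB5 (−1.76 ± 0.04 SE) and the ATPase gene PSMC3 (−1.54 ± 0.05). Genes of N-glycan biosynthesis fell in 31 of 45 cases and rose in 8 (median −0.41, adjusted p = 0.012), including the branching enzyme gene MGAT5 (−1.97 ± 0.05). Genes of the citrate cycle fell in 20 of 28 cases and rose in 4 (median −0.39, adjusted p = 0.0074). IDH2 fell by 2.14 ± 0.06, whereas PCK2, which encodes the mitochondrial phosphoenolpyruvate carboxykinase, rose by 2.17 ± 0.05. Circadian rhythm genes were the only pathway shifted upward among the 33, with 20 rises and 6 falls among 28 (median 0.60, adjusted p = 0.046). The nuclear receptor gene NR1D1 rose from 20.9 ± 0.55 to 93.8 ± 3.7 CPM and CRY2 by 1.14 ± 0.09. For several of the lists shifted in the report, related KEGG pathways were shifted the same way at the preset correlation. They included Ribosome, Oxidative phosphorylation, DNA replication, Cell cycle and Spliceosome. Glycolysis / Gluconeogenesis was among them too, with 10 rises and 33 falls among 44 (median −0.66, adjusted p = 0.0016). Other related pathways did not pass. The p53 signaling pathway had 30 rises and 33 falls among 65 (median −0.12, adjusted p = 0.96) and the NF-kappa B signaling pathway 34 rises and 29 falls among 78 (median 0.02, adjusted p = 0.65). Steroid biosynthesis had 4 rises and 9 falls among 19 (median −0.12, adjusted p = 0.43), Hippo signaling 57 rises and 54 falls among 127 (median 0.07, adjusted p = 0.85), HIF-1 signaling 32 rises and 40 falls among 85 (median −0.09, adjusted p = 0.76), glutathione metabolism 12 rises and 22 falls among 40 (median −0.30, adjusted p = 0.28) and RIG-I-like receptor signaling 24 rises and 23 falls among 51 (median 0.05, adjusted p = 0.74). The MAPK signaling pathway had 98 rises and 92 falls among 222 (median 0.05, adjusted p = 0.985). Apart from the fall of glycolytic genes, the matching list shifts did not pass in these related pathways, which hold partly other genes. Those shifts may therefore depend on the choice of genes, although a pathway that holds other genes does not test a list itself.

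The 6 libraries can be split into groups of 3 and 3 in 10 ways, too few for a share under 0.05. Each other split mixes the 2 groups, so that the difference between them widens the spread within each group of 3 and keeps the number of called genes low. A value of 0 there is therefore no measure of chance. For the number of changed genes 1 of the 10 splits, the real one, gave as many, with 10821 against 0 in the highest other split. That split value is from edgeR, where at most 28 genes in another split had an unadjusted p under 0.05. For genes changed at least 2-fold it was again 1 of 10, with 3158 against 0. For shifted lists it was 1 of 10, with 19 against 13 in the highest other split, and each of the other splits gave at least 9 lists at the preset correlation. The other splits mix the groups unevenly and so keep part of the difference between them. Their numbers of lists are therefore no measure of chance either.

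Ribosomal protein and oxidative phosphorylation genes fell together, with a median of −0.52 (bootstrap 95% interval −0.56 to −0.45). The intervals and random lists in this paragraph treat genes as independent. The estimated correlation between genes was 0.34 in the ribosomal protein list and 0.33 in the oxidative phosphorylation list. The intervals are therefore too narrow, and they do not cover the spread between libraries. A bias by length and GC as the whole cause was argued against by a median residual of −0.356 (−0.42 to −0.27) after a correction fitted on the other genes, although part of the fall went with the short length of these genes. A trend with abundance was argued against too, since the median lay at percentile 0 of 10000 random lists matched on mean level, whose lowest median was −0.37. Reads shared with pseudogenes as the whole cause were argued against for the oxidative phosphorylation genes, since the 17 with no pseudogene named after them in the RefSeq table had a median of −0.436 (−0.69 to −0.29), but cannot be told apart for the ribosomal protein genes, as 0 of 67 had no such pseudogene. An effect of the PPM1G shRNA itself stays open, as untested.

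A large programme of change stood beside a partial fall of PPM1G to 0.585 of its control level. Length or GC bias was argued against, as 93.0% of 3080 genes changed at least 2-fold kept a residual of that size. PPM1G shRNA libraries from an unrelated cell line were argued against by a stretch of very high levels on chromosome 7 (TES to WNT2, positions 116210539 to 117323058 on GRCh38), where the window of 7 genes around MET lay in the top 0.0232% of 17260 windows in both groups, at a median log2(FPKM + 1) of 7.92 and 8.25. In that window CAV1 stood at 9336 ± 335 and 10243 ± 87 CPM and MET at 7086 ± 167 and 3400.2 ± 18 CPM in the control and PPM1G shRNA libraries. What stays open, as untested, is PPM1G loss itself, effects of the hairpin on other transcripts, the type of control cells and differences in culture density or timing between the groups.

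PDGFRA was near 0, although NCI-H1703 is known as a line with amplified PDGFRA. It had 18 counts over the control libraries and 16 over the PPM1G shRNA libraries, or 0.175 ± 0.059 and 0.152 ± 0.040 CPM. Cells of another line under this name and a derivative that lost the amplified region cannot be told apart from levels alone. Copy number was not analysed here. In the control libraries 79.0% of windows lay at or above the PDGFRA window, and the highest windows lay around MET and CAV1. The window around FGFR1 on chromosome 8, also examined, held no such peak, with 27.8% of control windows at or above it. FGFR1 stood at 197 ± 2.0 CPM in the control and 167 ± 3.6 CPM in the PPM1G shRNA libraries. A missing peak at PDGFRA with a peak elsewhere was the pattern set for another line, but a derivative could show it too. Reads of PDGFRA lost in the counting stay open too, as untested. NKX2-1, a lung lineage transcription factor named after its values were seen, stood at 113.5 ± 7.3 and 121 ± 6.5 CPM.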
